A study of Arabidopsis thaliana with 30 samples.

How the data were processed

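Seeds of Arabidopsis thaliana were dissected from siliques at 8 and 12 days after flowering (DAF) from plants grown in 16 h light and 8 h dark at 22 °C, per the labels' protocols. The genotypes were Col-0 and fus3-3 in the Col-0 set, and WS, lec1-1 and lec2-1 in the WS set, the mutants homozygous, with 3 arrays for each of 10 groups from triplicate batches of plants, per the labels. Total RNA was extracted with Concert Plant RNA Reagent and cleaned with RNeasy, 2 µg were labelled as biotin cRNA with the One-Cycle kit, and the cRNA was hybridized to an Affymetrix Arabidopsis array of 22810 probe sets, per the labels' protocols. The arrays were processed with GCOS 1.3 and GCRMA, per the submitters' processing notes, and the deposited values are log2 signal. The version of GCRMA, and whether the 30 arrays were processed together, are not given in the sources used here. Array medians ran from 4.29 to 4.71 on the log2 scale, and the median standard deviation (SD) over genes within a group ran from 0.080 to 0.143. The replicate arrays of Col-0 at 12 DAF are numbered in 2 parts, of which the second was taken as the replicate number.

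Genes were named with the array annotation provided with the data and a TAIR10.1 gene table. Of the probe sets, 64 were controls, 13513 were paired with 1 gene (13436 of them with a gene that the table holds), 503 with several genes and 8730 with none. For each of 13355 genes, the single-gene probe set of highest mean in the set of arrays was kept, a choice that differed between the Col-0 set and the WS set for 8 genes. The deposited values were used as they are. Linear models were fitted to each set with limma 3.58.1 in R 4.3.3, with 1 mean per group and moderated variances (eBayes, no trend), and p-values were adjusted over all genes by the Benjamini-Hochberg method. Genes with an adjusted p under 0.05 and a change of at least 2-fold are described as past the threshold, called, risen or fallen. The comparisons were each mutant against its own wild type at each age, 12 against 8 DAF in each genotype, the difference between these age changes in mutant and wild type, and lec1-1 against lec2-1 at each age. The p-values of fus3-3 and of the lec mutants come from separate fits, and these effects were not tested against each other. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

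Gene lists were fixed before the data were examined: maturation regulators, seed storage proteins, oil body proteins, fatty acid and oil synthesis, LEA proteins, protein storage vacuole, raffinose oligosaccharides, small heat shock proteins, ABA metabolism and signalling, gibberellin, auxin, photosynthesis, lipid mobilisation, ER body, trichome formation, shoot meristem, cell cycle, flavonoid synthesis, cell wall loosening, endosperm markers, seed coat markers, silique wall markers and reference genes. Of the 447 genes of these 23 lists, 105 were measured by a single-gene probe set. Lists with at least 5 measured genes were tested with camera in limma against all other genes (preset correlation 0.01), with adjustment over 48 tests for the mutant comparisons, 40 for age, 24 for the difference of age changes and 16 for lec1-1 against lec2-1. Each list was tested again with a correlation estimated from its own genes.

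The genes to be named were set by a rule written before the data were examined. It took the mutated genes and ABI3 and L1L; for each mutant comparison the 6 largest rises and 6 largest falls among called genes whose arrays did not overlap between the groups and whose higher group mean was at least the median; up to 3 risen and 3 fallen members of each list, or the members of highest mean; and 4 and 4 genes for each other comparison. LEC1, LEC2, FUS3, ABI3 and L1L had no single-gene probe set in the annotation used and were not analysed here. Beyond that rule, further list members are given as examples and were chosen after their values were seen.

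The alternatives tried were quantile normalization again, centring each array on the 9 measured of 12 reference genes, all probe sets except controls, genes above the 40th percentile of mean signal, only the arrays of the groups compared, all 30 arrays in 1 fit, the replicate number as a block, trended and robust variances, no fold minimum, an adjusted p under 0.01, and leaving out each array in turn. For lists they were the estimated correlation, the rotation test fry, centring, the block and leaving out each array. Whether replicate numbers pair arrays was checked by the correlation of deviations from group means. In no comparison but fus3-3 at 12 against 8 DAF did all 3 exceed 0.1. There these were 0.25, 0.22 and 0.45 for the same numbers, so that comparison was also read with the block. The block was fitted over all 12 arrays of the Col-0 set, and no paired fit of the fus3-3 arrays alone was made.

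Overlaps of calls were set against n1 × n2 / N for independent lists, and for lec1-1 and lec2-1 against 100 simulations of unchanged groups with shared WS arrays. Each count was recomputed over other splits of the same arrays, all 10 for 2 groups of 3 and 100 for the differences of age changes. The scripts were tested on simulated data of 13355 genes with known changes. For fus3-3 against Col-0 at 8 DAF they called 61 of 67 genes changed by 1.5 log2 units, 65 of 66 changed by 3 and 0 of 67 changed by 0.5, with 2 false calls, and for lec2-1 against WS at 8 DAF 64 of 67 and 66 of 66, with 1 false call. Probe sets paired with several genes or none were left out of the comparisons and are counted in the closing section.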

Results

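Transcript levels were measured in developing seeds of Arabidopsis thaliana, taken out of the fruit (silique) at 8 and 12 days after flowering (DAF), in the wild types Col-0 and WS and in plants homozygous for the fus3-3, lec1-1 or lec2-1 mutation. FUS3 and LEC2 are B3-domain transcription factors and LEC1 is a subunit of the NF-Y transcription factor complex, and all of them are master regulators of seed maturation, the phase in which the seed fills with reserves and becomes tolerant of drying. The question of the design was which seed genes depend on these regulators, with each mutant set against the wild type of its own background. Each of the 10 groups had 3 arrays, called biological replicates from triplicate batches of plants in the labels, so that 12 arrays belonged to the Col-0 set (Col-0 and fus3-3) and 18 to the WS set (WS, lec1-1 and lec2-1). The Col-0 arrays at 12 DAF are numbered in 2 parts. Their median SD over genes was 1.34 times the median of the other 9 groups, which met what was set against 3 arrays of 1 RNA sample. No arrays known to share 1 RNA sample were at hand for comparison, so the spread does not settle that. Whether they came from separate batches of plants is not settled by that spread either. If they did not, the p-values of comparisons with that group measure only the spread between its arrays. The array medians lay between 4.29 and 4.71 on the deposited log2 scale, and replicate arrays of a group correlated at r of 0.984 to 0.996 over genes, which are not independent replicates. With 3 arrays per group, the number of arrays limits the precision of every value below.

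The regulators LEC1, LEC2, FUS3 and ABI3, and the LEC1 relative L1L, were not analysed here, because no probe set was paired with any of them alone in the annotation used. The genotype labels were therefore not checked against the mutated genes. A gene was called higher or lower at an adjusted p below 0.05 and a change of at least 2-fold, and ± after a log2 change is its standard error (SE) from the fit, with n = 3 arrays per group throughout. Genes are listed by the fitted log2 change. Where the lower group's log2 signal lay under 3, toward the array minima of 1.65 to 1.76, that change is read as a lower bound, and the order among such genes is not read. In the 6 mutant comparisons, the 3' minus 5' signal of the actin control, a sign of RNA quality, was higher in the mutant by over 1 SD in 5, with a highest difference of 1.04 in fus3-3 at 12 DAF, and that of GAPDH was lower by over 1 SD in 4.

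At 8 DAF, genes of the ER body, an endoplasmic reticulum compartment that holds β-glucosidases in seedlings and roots, were far higher in fus3-3 seeds than in Col-0 seeds, and a storage globulin gene was far lower. PYK10 (AT3G09260), the main β-glucosidase of the ER body, was 185-fold higher, with a log2 signal of 11.98 ± 0.23 (SD, n = 3) in fus3-3 against 4.45 ± 0.36 in Col-0 (adjusted p = 8.7e-08). AT1G03890, of the cruciferin family of storage globulins, fell from 10.77 ± 0.50 to 2.18 ± 0.12 (adjusted p = 2.3e-07). Further rises were those of ZW9 (AT1G58270) at 6.94 ± 0.12, AT2G47780 at 6.78 ± 0.49, the jacalin-related lectin gene JAL34 (AT3G16460) at 6.55 ± 0.13 and the late embryogenesis abundant (LEA) genes AT3G15670 and AT4G36600 at 6.47 ± 0.35 and 6.27 ± 0.50 log2 units. Beside AT1G03890, falls were those of AT1G76470 at −6.33 ± 0.34, AT5G08460 at −6.19 ± 0.27, AT3G25160 at −6.01 ± 0.21, AT4G25980 at −5.78 ± 0.42 and AT1G26680 at −5.76 ± 0.20.

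Of 20 planned ER body genes, 7 were measured. Of these 7 genes, 5 rose in fus3-3 at 8 DAF, among them NAI2 (AT3G15950), a component of the ER body, by 5.77 ± 0.29 and JAL33 (AT3G16450) by 5.52 ± 0.17. NAI1 (AT2G22770), a bHLH factor needed for ER body formation, also rose (adjusted p = 0.0030). The list stood above the other genes, at adjusted p = 8.0e-10, and adjusted p = 0.017 with an estimated correlation. Of 20 LEA genes, which encode protective proteins of the drying seed, 12 rose and 0 fell, including LEA18 (AT2G35300) by 5.74 ± 0.24 and LEA4-5 (AT5G06760) by 5.34 ± 0.27. This shift gave adjusted p = 1.5e-10, and adjusted p = 0.13 with an estimated correlation. Photosynthesis genes were measured in 11 of 60 planned cases. Of these 11 genes, 6 fell and 0 rose, among them the antenna gene LHCB4.3 (AT2G40100) at −2.98 ± 0.28, PRK (AT1G32060), which encodes phosphoribulokinase, at −1.96 ± 0.21 and PSBY (AT1G67740) at −1.47 ± 0.13. Adjusted over the list alone, 7 fell, with ATPC1 at −1.25 ± 0.47 added. The camera test of the photosynthesis list gave adjusted p = 5.9e-08, and adjusted p = 0.060 with an estimated correlation.

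Of 13 planned seed storage genes, 5 were measured, and the SESA genes, CRA1, CRU2 and CRU3 were not among them. Of these 5 genes, 3 fell in fus3-3 at 8 DAF, with PAP85 (AT3G22640), a vicilin-like gene, at −1.82 ± 0.30 and AT4G36700 at −1.29 ± 0.22 beside AT1G03890. For the whole list, camera gave adjusted p = 0.00012, and adjusted p = 0.13 with an estimated correlation. Among 4 oil body genes, AT2G25890 rose by 1.52 ± 0.31 while AT3G18570 and AT3G01570 changed by −1.27 ± 0.30 and −1.23 ± 0.20. Among 4 maturation regulators, the MADS-box gene AGL67 (AT1G77950) and the bZIP gene EEL (AT2G41070) fell, at −2.41 ± 0.25 and −1.85 ± 0.22. The Aux/IAA gene IAA31 (AT3G17600), 1 of 5 measured auxin genes, fell, at −1.83 ± 0.39. That list had adjusted p = 0.046, and adjusted p = 0.14 with an estimated correlation, and its call ended without fus3-3 replicate 1 (0.071), without fus3-3 replicate 2 (0.060), without Col-0 replicate 3 (0.077) or with centring on reference genes (0.056). The call also ended with the replicate number as a block. Other list members past the threshold were the flavonoid glycosyltransferase gene UGT78D2 at −1.21 ± 0.26, BETA-VPE, which encodes a vacuolar processing enzyme, at −1.47 ± 0.17, the xyloglucan enzyme gene XTH16 at 1.13 ± 0.25 and the seed coat marker AT3G50990 at −2.06 ± 0.29. In all, 1105 of 13355 genes passed the threshold at 8 DAF, 538 higher and 567 lower.

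At 12 DAF, most measured ER body genes stood higher still against Col-0, and most measured photosynthesis genes were now higher in fus3-3. The measured reserve genes and 12 of 20 LEA genes were lower. PYK10 had a log2 signal of 12.71 ± 0.25 (SD, n = 3) in fus3-3 and 2.49 ± 0.04 in Col-0, a change of 10.22 ± 0.19 (adjusted p = 1.3e-09). NAI2 rose by 8.33 ± 0.29, JAL33 by 8.18 ± 0.17 and JAL34 by 8.05 ± 0.13, and further rises were those of AT2G47780 at 8.46 ± 0.49 and AT4G23670 at 8.14 ± 0.26. AT3G05260 fell, at −9.28 ± 0.55 (adjusted p = 1.2e-06), from 13.03 ± 0.24 in Col-0 to 3.75 ± 0.56. Other falls were those of AT2G38900 at −8.28 ± 0.25, AT3G17130 at −8.08 ± 0.45, AT1G29680 at −7.64 ± 0.52, AT1G33700 at −7.57 ± 0.18 and AT5G04380 at −7.44 ± 0.36.

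Of the 7 ER body genes, 6 rose in fus3-3 at 12 DAF, with JAL22 (AT2G39310) at 5.53 ± 0.27 and NAI1 at 3.41 ± 0.22, and JAL23 stood at −0.04 ± 0.06. As a group, these genes had adjusted p = 7.3e-08, and adjusted p = 0.019 with an estimated correlation. Of 11 photosynthesis genes, 8 rose and 1 fell. ATPC1 (AT4G04640), the chloroplast ATP synthase γ subunit gene, rose by 3.27 ± 0.47, the photosystem I gene PSAE-1 (AT4G28750) by 2.81 ± 0.18 and LHCB4.2 (AT3G08940) by 2.60 ± 0.37, while LHCB4.3 fell, at −3.78 ± 0.28. The list test gave adjusted p = 0.00023, and adjusted p = 0.15 with an estimated correlation. In the same arrays ALC (AT5G67110), the 1 measured silique wall marker, rose by 1.67 ± 0.26, and MPC (AT3G19350), 1 of 3 measured endosperm markers, by 3.05 ± 0.15. Of the 5 flavonoid genes, 3 rose, AT4G14090 by 3.47 ± 0.24, the anthocyanin glycosyltransferase gene UF3GT by 3.13 ± 0.12 and DFR, which encodes dihydroflavonol reductase, by 1.57 ± 0.36. Over all its members, the list had adjusted p = 0.0051, and adjusted p = 0.13 with an estimated correlation.

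All 5 measured storage genes fell in fus3-3 at 12 DAF, from AT2G18540 at −1.22 ± 0.25 to AT1G03890 at −6.29 ± 0.27 (adjusted p = 0.0034, and adjusted p = 0.21 with an estimated correlation), and so did all 4 oil body genes, with AT3G18570 at −3.62 ± 0.30 and the oleosin gene OLEO3 (AT5G51210) at −2.37 ± 0.32. The acyl-ACP thioesterase gene FaTA (AT3G25110) fell, at −3.82 ± 0.17, whereas FATB stood at −0.43 ± 0.21. Of 20 LEA genes, 12 fell and 3 rose, with M10 at −5.89 ± 0.59, M17 at −4.35 ± 0.69 and AT3G53040 at −3.12 ± 0.44 against AT4G36600 at 3.35 ± 0.50 and LEA18 at 2.32 ± 0.24, and the list as a whole did not pass (adjusted p = 0.13). All 4 measured regulators fell, AGL67 at −5.66 ± 0.25, the AP2 gene BBM (AT5G17430) at −3.43 ± 0.25, EEL at −2.25 ± 0.22 and BZIP53 at −1.33 ± 0.17. Of the auxin genes, IAA31, IAA30 and YUC4, an auxin synthesis gene, fell, at −4.18 ± 0.39, −2.76 ± 0.22 and −1.80 ± 0.22 (list adjusted p = 0.060).

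Single members of other lists also passed the threshold in fus3-3 at 12 DAF. The small heat shock genes AT1G53540, AT5G37670 and AT2G29500 fell, at −2.36 ± 0.30, −1.61 ± 0.27 and −1.17 ± 0.29, and BETA-VPE fell, at −1.89 ± 0.17. The replication helicase gene PRL (AT4G02060) rose (adjusted p = 3.3e-08). Rises were also seen for the Aurora kinase gene AUR1, by 1.48 ± 0.16, XTH16 by 3.89 ± 0.25 and the gibberellin receptor gene GID1B by 1.47 ± 0.25, while the expansin gene EXPA15 fell, at −2.78 ± 0.37. In all, 3130 of 13355 genes passed the threshold, 1595 higher and 1535 lower, against 1105 at 8 DAF.

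**Figure D1:**
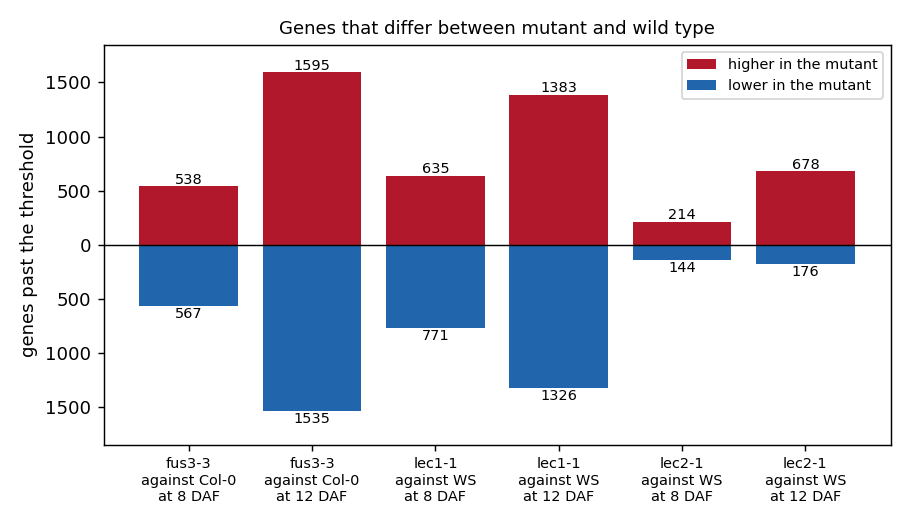
Number of genes past the threshold (y axis) in each mutant against its own wild type at 8 and 12 DAF (x axis), with separate bars for higher and lower genes out of 13355 tested. The count rose between the ages from 1105 to 3130 in fus3-3, from 1406 to 2709 in lec1-1 and from 358 to 854 in lec2-1.

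In lec1-1 at 8 DAF, the ER body genes PYK10, JAL34 and NAI2 were among the rises over WS, and AT5G22810 was among the falls. PYK10 rose by 9.44 ± 0.16, to 11.96 ± 0.14 (SD, n = 3) from 2.52 ± 0.03 (adjusted p = 1.8e-13), JAL34 rose by 7.90 ± 0.20 and NAI2 by 6.97 ± 0.21. AT4G29030, AT2G47780 and AT5G19100 rose by 6.86 ± 0.28, 6.74 ± 0.21 and 6.56 ± 0.20. AT5G22810 fell, at −7.44 ± 0.14 (adjusted p = 3.1e-13), from 10.15 ± 0.09 in WS to 2.71 ± 0.10. Falls were also seen for AT3G25160 at −6.70 ± 0.18, AT1G71691 at −6.60 ± 0.27, AT1G26680 at −5.79 ± 0.16, AT5G10580 at −5.75 ± 0.21 and AT5G38195 at −5.05 ± 0.14.

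Of the 7 ER body genes, 5 rose in lec1-1 at 8 DAF, with JAL22 at 3.46 ± 0.25 and NAI1 at 2.19 ± 0.31. Camera put the list at adjusted p = 1.7e-07, and adjusted p = 0.017 with an estimated correlation. JAL33, which rose in fus3-3, stood at 0.16 ± 0.13 in lec1-1. Its signal lay between 2.60 and 3.49 on all 18 arrays of the WS set. Whether its probe set can show a rise in that background is not known. The fus3-3 and lec1-1 effects were not tested against each other. Of 20 LEA genes, 9 rose and 2 fell, with LEA18 at 5.19 ± 0.17, AT4G36600 at 5.16 ± 0.31 and AT3G15670 at 4.86 ± 0.11 above, and the gene annotated LEA (AT2G21490) and AT5G44310 below, at −2.03 ± 0.18 and −1.38 ± 0.15. Set against other genes, the list had adjusted p = 0.00013, and adjusted p = 0.27 with an estimated correlation. Of 11 photosynthesis genes, 6 fell and 0 rose, among them PRK at −1.97 ± 0.17, LHCB4.3 at −1.89 ± 0.13 and PSAN, of photosystem I, at −1.53 ± 0.17. The list had adjusted p = 3.9e-07, and adjusted p = 0.060 with an estimated correlation. Of 5 flavonoid genes, UF3GT and AT4G14090 rose, by 3.53 ± 0.39 and 3.41 ± 0.21. The list had adjusted p = 0.032, and adjusted p = 0.27 with an estimated correlation, and its call ended without lec1-1 replicate 1 (0.057), without WS replicate 3 (0.076) or with centring on reference genes (0.24).

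Storage genes fell in lec1-1 at 8 DAF in 4 of 5 cases, with AT1G03890 at −4.03 ± 0.10, AT2G28490 at −2.05 ± 0.11, AT2G18540 at −1.39 ± 0.21 and PAP85 at −1.21 ± 0.06. Their camera test gave adjusted p = 1.1e-07, and adjusted p = 0.019 with an estimated correlation. Oil body genes fell in 3 of 4 cases, AT3G18570 at −1.94 ± 0.12, OLEO3 at −1.52 ± 0.09 and AT3G01570 at −1.35 ± 0.11, and FaTA fell, at −1.95 ± 0.16. Of the regulators, AGL67, BBM and EEL fell, at −3.14 ± 0.30, −2.72 ± 0.30 and −1.96 ± 0.13. IAA31 and YUC4 fell, at −2.03 ± 0.17 and −1.09 ± 0.26, though the auxin list had a median of 0.01 and a mean of −0.55 (adjusted p = 0.38). PRL rose by 1.97 ± 0.33 and XTH16 by 1.95 ± 0.21, while EXPA15 and ICL, which encodes isocitrate lyase, fell, at −1.45 ± 0.13 and −1.42 ± 0.15. In all, 1406 genes passed the threshold, 635 higher and 771 lower. After centring on reference genes the split was 875 higher and 519 lower.

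At 12 DAF, lec1-1 seeds kept high ER body transcripts and had far more photosynthesis transcripts than WS seeds. PYK10 rose by 9.70 ± 0.16, to 12.18 ± 0.06 (SD, n = 3) from 2.48 ± 0.05 (adjusted p = 4.6e-14). PORB (AT4G27440), the protochlorophyllide oxidoreductase of chlorophyll synthesis, rose to 11.95 ± 0.19 from 2.79 ± 0.70 (adjusted p = 4.9e-11), and the thionin gene THI2.1 (AT1G72260) rose by 9.05 ± 0.19 (adjusted p = 3.7e-13). AT1G09750, AT2G47780 and JAL34 rose by 8.38 ± 0.19, 8.20 ± 0.21 and 7.99 ± 0.20. AT5G22810 fell again, at −8.36 ± 0.14 (adjusted p = 4.6e-14), as did AT1G71691 at −6.80 ± 0.27, AT4G19380 at −6.12 ± 0.18, AT1G49310 at −5.54 ± 0.22, AT3G25160 at −5.48 ± 0.18 and AT4G22730 at −5.42 ± 0.22.

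Of 11 photosynthesis genes, 10 rose in lec1-1 at 12 DAF, with LHCB4.2 at 5.87 ± 0.23, ATPC1 at 5.83 ± 0.16 and PSBW, of photosystem II, at 5.59 ± 0.22. LHCB4.3 was the exception and fell, at −2.68 ± 0.13. For the whole list, camera gave adjusted p = 1.5e-10, and adjusted p = 0.019 with an estimated correlation. The mean log2 signal of the list was 10.45 ± 0.03 (SD, n = 3) in lec1-1 and 6.56 ± 0.13 in WS. In the same arrays the silique wall marker ALC rose by 2.06 ± 0.19 and the endosperm marker MPC by 3.39 ± 0.33. ER body genes rose in 6 of 7 cases, with NAI2 at 7.95 ± 0.21, JAL22 at 6.42 ± 0.25 and JAL23 at 1.51 ± 0.14. As a group, these genes had adjusted p = 5.9e-08, and adjusted p = 0.017 with an estimated correlation. All 5 flavonoid genes rose, UF3GT by 5.36 ± 0.39, AT4G14090 by 5.23 ± 0.21, DFR by 4.84 ± 0.26, the anthocyanin malonyltransferase gene AT5MAT by 3.76 ± 0.22 and UGT78D2 by 1.11 ± 0.24. The list test gave adjusted p = 1.1e-05, and adjusted p = 0.046 with an estimated correlation.

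Most measured reserve genes stayed lower in lec1-1 at 12 DAF. Storage genes fell in 4 of 5 cases, from AT1G03890 at −1.11 ± 0.10 to AT4G36700 at −3.26 ± 0.09 (adjusted p = 0.0026, and adjusted p = 0.15 with an estimated correlation), and PAP85 stood at −0.72 ± 0.06. All 4 oil body genes fell, with AT3G18570 at −2.53 ± 0.12 and OLEO3 at −2.51 ± 0.09, and FaTA fell, at −4.32 ± 0.16. Of 20 LEA genes, 9 fell and 3 rose, with the gene annotated LEA at −1.90 ± 0.18 and AT3G53040 at −1.78 ± 0.30 against AT4G36600 at 3.09 ± 0.31 and LEA18 at 2.31 ± 0.17, and the list did not pass (adjusted p = 0.59). AGL67, BBM and EEL fell, at −3.81 ± 0.30, −3.22 ± 0.30 and −2.33 ± 0.13, as did IAA31, IAA30 and YUC4, at −2.97 ± 0.17, −2.28 ± 0.16 and −1.98 ± 0.26 (auxin list adjusted p = 0.056). PRL rose by 4.56 ± 0.33, XTH16 by 2.58 ± 0.21, GID1B by 1.81 ± 0.24 and AUR1 by 1.57 ± 0.25, while EXPA15, DELTA-VPE and BETA-VPE fell, at −1.58 ± 0.13, −2.38 ± 0.18 and −1.48 ± 0.10. In all, 2709 genes passed the threshold, 1383 higher and 1326 lower. Centred on reference genes, the split was 1863 higher and 829 lower, and the median change of all genes moved from −0.11 to 0.21.

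**Figure D2:**
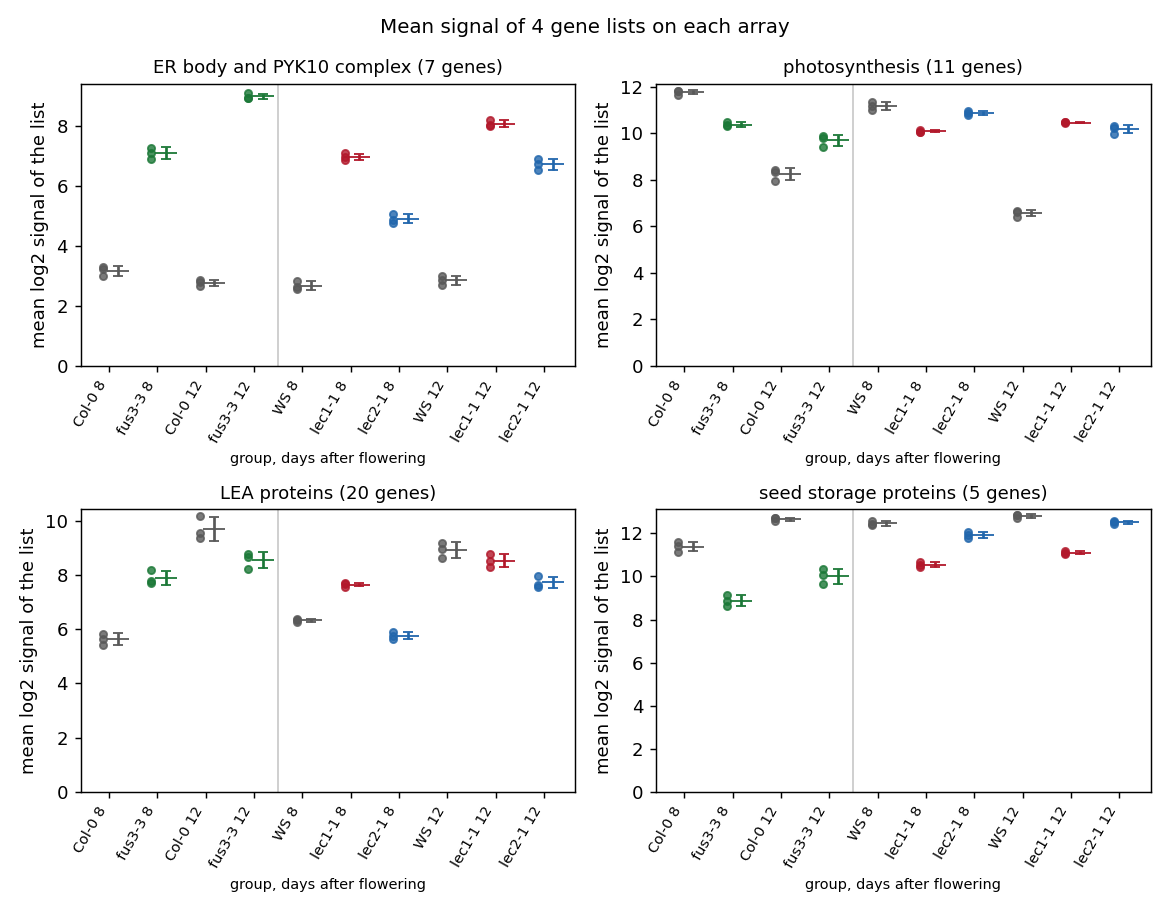
Mean log2 signal (y axis) of the measured genes of the ER body, photosynthesis, LEA and seed storage lists in the 10 groups (x axis). Points are single arrays, and bars give the mean ± SD of the 3 arrays of a group. The ER body mean was 2.86 ± 0.15 in WS at 12 DAF, 8.09 ± 0.12 in lec1-1 and 6.74 ± 0.18 in lec2-1.

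In lec2-1 at 8 DAF, fewer genes differed from WS, and ER body genes were again among the rises. AT4G29030 was 107-fold higher, at 10.42 ± 0.17 (SD, n = 3) against 3.67 ± 0.79 (adjusted p = 4.2e-09), and PYK10 rose to 8.04 ± 0.26 from 2.52 ± 0.03 (adjusted p = 4.5e-11). AT4G23670, AT4G29570, NAI2 and AT4G29640 rose by 5.79 ± 0.29, 5.34 ± 0.25, 5.16 ± 0.21 and 5.07 ± 0.13. The LEA-type gene AT3G17520, at 10.43 ± 0.15 in WS, changed by −8.12 ± 0.13 and so fell to near the floor of the array (adjusted p = 1.4e-13), and AT3G27420 fell to 2.47 ± 0.08 from 7.88 ± 0.24 (adjusted p = 2.6e-11). The following falls were smaller, AT3G15630 at −2.61 ± 0.33, AT1G75490 at −2.54 ± 0.22, the tetraspanin gene TET4 at −2.45 ± 0.25 and AT5G04380 at −2.32 ± 0.23.

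Of the 7 ER body genes, 3 rose in lec2-1 at 8 DAF, with JAL34 at 4.21 ± 0.20 beside PYK10 and NAI2. Over all its members, the list had adjusted p = 1.9e-07, and adjusted p = 0.017 with an estimated correlation. UF3GT and AT4G14090, of the flavonoid list, rose by 2.06 ± 0.39 and 1.72 ± 0.21. Camera put the list at adjusted p = 0.0045, and adjusted p = 0.15 with an estimated correlation. None of the 5 storage genes passed the threshold, adjusted over all genes or over the list alone, with AT1G03890 at −0.81 ± 0.10 and AT2G18540 at −0.73 ± 0.21, yet the list lay below the other genes by a median of −0.51. Set against other genes, the list had adjusted p = 7.5e-06, and adjusted p = 0.046 with an estimated correlation. None of the 11 photosynthesis genes passed it either, with LHCB4.2 at −0.64 ± 0.23, and the list had a median of −0.29 (adjusted p = 0.0027, and adjusted p = 0.21 with an estimated correlation), a call that ended without WS replicate 1 (0.057). Of 20 LEA genes, 3 fell, AT3G17520, AT5G44310 at −1.24 ± 0.15 and the gene annotated LEA at −1.23 ± 0.18. The list had adjusted p = 0.023, adjusted p = 0.53 with an estimated correlation, and 0.054 without WS replicate 1. AT3G17520, at −8.12 ± 0.13, was part of that test, which was not repeated without it. BBM and AGL67 fell, at −1.57 ± 0.30 and −1.16 ± 0.30, and YUC4 fell, at −1.01 ± 0.26 (auxin list adjusted p = 0.46), while PRL rose by 1.48 ± 0.33. In all, 358 genes passed the threshold, 214 higher and 144 lower.

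At 12 DAF, the lec2-1 rises included THI2.1, PORB and other genes that were low in WS seeds. THI2.1 rose to 12.60 ± 0.17 (SD, n = 3) from 2.93 ± 0.13 (adjusted p = 7.8e-13), and PORB rose to 10.24 ± 0.52 from 2.79 ± 0.70 (adjusted p = 1.3e-09). AT3G28220 rose by 7.88 ± 0.25, AT4G29030 by 7.45 ± 0.28, AT3G16370 by 7.01 ± 0.17 and AT1G09750 by 6.87 ± 0.19. AT3G17520 fell, at −10.82 ± 0.13 (adjusted p = 3.1e-15), from 13.15 ± 0.17 in WS to 2.33 ± 0.06, and AT3G27420 fell, at −5.63 ± 0.15, from 8.04 ± 0.22 to 2.40 ± 0.05. Beside them, falls were those of AT1G49310 at −4.59 ± 0.22, M10 at −4.07 ± 0.49, the defensin-like gene LCR67 (AT1G75830), 7.99-fold lower (adjusted p = 1.2e-05), and AT3G15250 at −2.88 ± 0.17.

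Of 11 photosynthesis genes, 10 rose and 0 fell in lec2-1 at 12 DAF, with PSBW at 5.16 ± 0.22, PSAN at 4.96 ± 0.17 and ATPC1 at 4.93 ± 0.16, and LHCB4.3 stood at −0.29 ± 0.13. The list had adjusted p = 1.1e-20, and adjusted p = 0.0064 with an estimated correlation. The silique wall marker ALC rose by 1.57 ± 0.19 in these arrays, and the endosperm marker MPC stood at 0.87 ± 0.33. ER body genes rose in 6 of 7 cases, NAI2 by 6.61 ± 0.21, PYK10 by 6.39 ± 0.16 and JAL34 by 4.78 ± 0.20. Their camera test gave adjusted p = 7.4e-12, and adjusted p = 0.0064 with an estimated correlation. All 5 flavonoid genes rose, with DFR at 5.18 ± 0.26, UF3GT at 4.28 ± 0.39 and AT4G14090 at 4.27 ± 0.21. For the whole list, camera gave adjusted p = 6.0e-09, and adjusted p = 0.017 with an estimated correlation.

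The measured reserve genes, 5 of 13 planned for storage and 4 of 13 planned for oil bodies, differed little in lec2-1 at 12 DAF. None of the 5 storage genes passed the threshold (list adjusted p = 0.49), with AT1G03890 at −0.11 ± 0.10 and PAP85 at 0.03 ± 0.06, nor did any of the 4 oil body genes, with OLEO3 at −0.10 ± 0.09. FaTA fell, at −1.16 ± 0.16. Of 20 LEA genes, 5 fell, AT3G17520, M10, AT3G22490 at −1.64 ± 0.27, M17 at −1.61 ± 0.27 and AT3G53040 at −1.07 ± 0.30. The list had adjusted p = 0.023, adjusted p = 0.53 with an estimated correlation, and 0.096 without WS replicate 1. AT3G17520, at −10.82 ± 0.13, was part of that test too, which was not repeated without it. BBM and YUC4 fell, at −2.36 ± 0.30 and −1.35 ± 0.26 (auxin list adjusted p = 0.063). PRL rose by 2.46 ± 0.33, GID1B by 1.19 ± 0.24 and TRY, which restrains trichome formation, by 1.31 ± 0.15. In all, 854 genes passed the threshold, 678 higher and 176 lower.

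**Figure D3:**
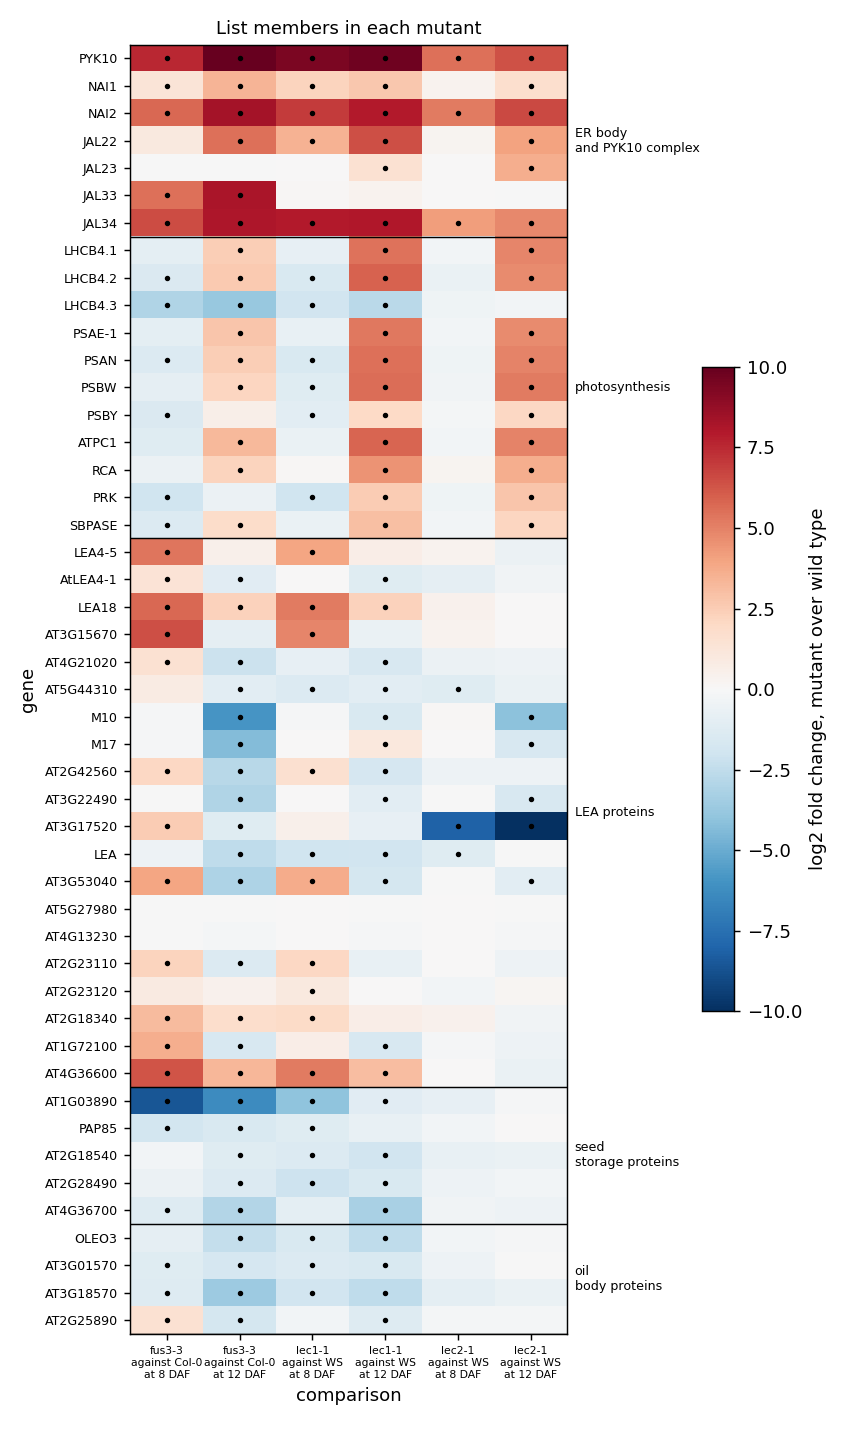
Log2 change (colour) of the measured members of 5 gene lists in each mutant against its own wild type at 8 and 12 DAF. Dots mark members past the threshold. 10 of 11 photosynthesis genes were higher in lec1-1 and in lec2-1 at 12 DAF, and 8 in fus3-3.

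**Figure D4:**
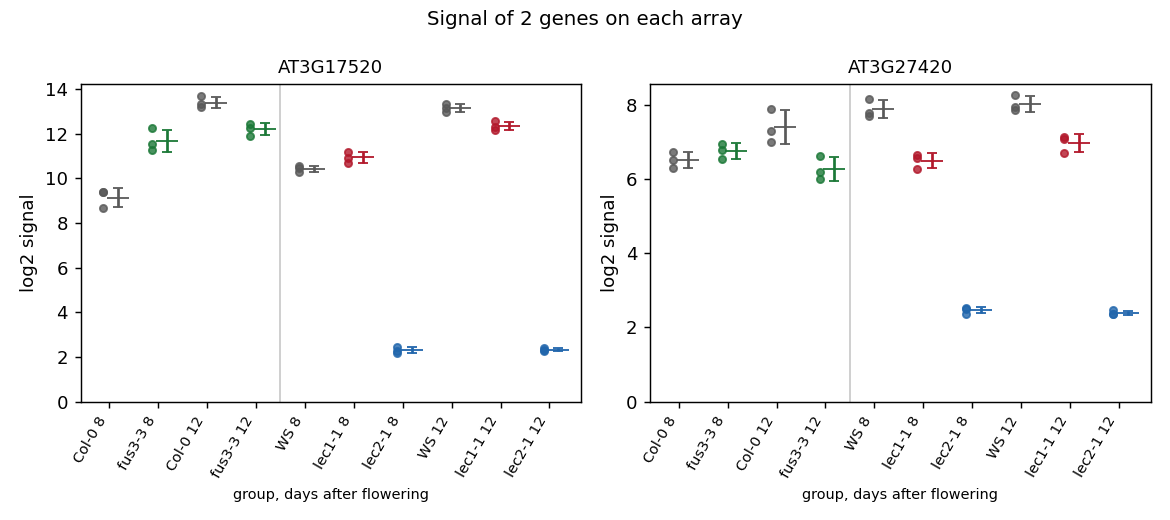
Log2 signal (y axis) of AT3G17520 and AT3G27420 on each array of the 10 groups (x axis), with points for arrays and bars for the mean ± SD of 3 arrays. At 12 DAF, AT3G17520 stood at 2.33 ± 0.06 in lec2-1 and 12.35 ± 0.20 in lec1-1.

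The remaining lists moved little in the 6 mutant comparisons or held few measured genes. Of the 6 cell wall loosening genes, XTH16 and EXPA15 were the members past the threshold, and the list passed in no comparison (adjusted p from 0.34 to 0.95). Its median and mean differed in sign in fus3-3 at 12 DAF (−0.03 and 0.31), lec1-1 at 12 DAF (−0.07 and 0.14) and lec2-1 at 12 DAF (−0.05 and 0.10), and at 8 DAF in lec2-1 they were 0.00 and −0.02. Of the 9 reference genes, which also serve for the centring, AT2G28390 passed the threshold in lec1-1 at 12 DAF with a value of −1.08 ± 0.09, and the list passed in no comparison. In lec2-1 at 12 DAF its median was −0.08 while the test pointed up (adjusted p = 0.68). The flavonoid list in fus3-3 at 8 DAF had a median of 0.01 and a mean of −0.16 (adjusted p = 0.92). The meristem gene CLV3, 1 of 17 planned, lay between −0.08 ± 0.02 and 0.00 ± 0.02, the seed coat genes BAN and ARA12 passed the threshold in no mutant comparison, and neither did the endosperm genes AGL62 and IKU2. ALPHA-VPE, AUR2, the small heat shock gene ATHSP22.0, the gibberellin genes GID1A, GID1C and SPY and the lipid mobilisation genes AIM1, SDP1 and SDP1-LIKE did not pass it either. No member of the raffinose list or of the abscisic acid (ABA) list was measured. Counts adjusted over the list alone equalled those over all genes in these comparisons, apart from the photosynthesis list in fus3-3 at 8 DAF.

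Between 8 and 12 DAF, photosynthesis genes fell and LEA genes rose in both wild types. All 11 photosynthesis genes fell in Col-0 and in WS, with PSAN at −4.71 ± 0.29 and −6.32 ± 0.17 and ATPC1 at −4.71 ± 0.47 and −6.19 ± 0.16. The list had adjusted p = 7.3e-12 in Col-0, and adjusted p = 0.071 with an estimated correlation, and adjusted p = 3.0e-16 in WS, and adjusted p = 0.029 with an estimated correlation. In the mutants 1 member fell in fus3-3 and in lec2-1, which was LHCB4.3 in each, at −2.83 ± 0.28 and −1.30 ± 0.13, and in lec1-1 LHCB4.2 rose by 1.93 ± 0.23 while LHCB4.3 fell, at −2.25 ± 0.13. The estimated correlation gave adjusted p = 0.29, 0.16 and 0.42 for the list in fus3-3, lec2-1 and lec1-1, against 0.0016, 0.00013 and 0.020 with the preset correlation. LEA genes rose in 17 of 20 cases in Col-0 and 16 in WS, AT3G15670 by 7.57 ± 0.35 and 5.67 ± 0.11, against 2 in fus3-3, 8 in lec1-1 and 12 in lec2-1. These LEA shifts had adjusted p of 6.8e-11, 3.0e-08, 0.0057, 0.00057 and 3.2e-09 in that order of genotypes, and adjusted p of 0.16, 0.16, 0.55, 0.42 and 0.16 with an estimated correlation.

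Rises with age in Col-0 included those of AT1G14940 at 10.31 ± 0.54, AT1G14930 at 10.22 ± 0.42, AT3G58550 at 10.14 ± 0.34 and the β-glucosidase gene BGLU19 (AT3G21370) at 10.08 ± 0.33, and falls those of GILT (AT4G12960) at −9.71 ± 0.34, ATPMEPCRD (AT2G43050) at −9.27 ± 0.31, AT1G09750 at −8.83 ± 0.28 and AT5G60630 at −8.17 ± 0.35. In WS, BGLU19 rose by 10.99 ± 0.23, AT1G14940 by 10.73 ± 0.14, AT1G14930 by 10.07 ± 0.25 and AT3G21380 by 9.90 ± 0.24, while AT1G62070, AT1G09750, the subtilase gene SBTI1.1 (AT1G01900) and GILT fell, at −8.95 ± 0.17, −8.55 ± 0.19, −7.70 ± 0.26 and −6.93 ± 0.28. All 4 also rose in both lec mutants, BGLU19, AT3G21380 and AT1G14930 by 10.07 ± 0.23, 9.61 ± 0.24 and 9.40 ± 0.25 in lec2-1, and BGLU19 and AT1G14940 by 9.93 ± 0.23 and 9.67 ± 0.14 in lec1-1, and AT3G05260 rose by 9.28 ± 0.45 in lec2-1. In lec1-1, AT1G62070, SBTI1.1, GILT and AT5G49180 fell, at −9.22 ± 0.17, −8.08 ± 0.26, −7.52 ± 0.28 and −7.14 ± 0.13. In lec2-1, AT1G62070, GILT, SBTI1.1 and the endoglucanase gene GH9C1 fell, at −9.03 ± 0.17, −7.74 ± 0.28, −7.23 ± 0.26 and −7.09 ± 0.09. In fus3-3, AT1G14950 rose by 9.18 ± 0.24, AT3G58550 by 7.63 ± 0.34, AT1G14930 by 7.35 ± 0.42 and FACT (AT5G63560) by 7.28 ± 0.30, and AT1G62070, GILT, ATPMEPCRD and AT2G38900 fell, at −9.34 ± 0.57, −8.36 ± 0.34, −8.16 ± 0.31 and −7.19 ± 0.25.

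ER body genes rose with age in fus3-3 in 5 of 7 cases, in lec2-1 in 4 and in lec1-1 in 2, with JAL22 at 4.87 ± 0.27, 4.48 ± 0.25 and 3.69 ± 0.25 (adjusted p = 3.7e-07, 0.00040 and 0.0026, and adjusted p = 0.071, 0.16 and 0.16 with an estimated correlation). In Col-0, PYK10 and NAI2 fell, at −1.96 ± 0.19 and −1.01 ± 0.29, and no member passed the threshold in WS. The list's median was 0.02 and its mean −0.40 in Col-0 (adjusted p = 0.27). Flavonoid genes rose in 4 of 5 cases in lec1-1 and in lec2-1 and in 2 in fus3-3, with UF3GT at 1.85 ± 0.39, 2.24 ± 0.39 and 2.69 ± 0.12 (adjusted p = 0.00036, 0.0018 and 0.0057, and adjusted p = 0.16 for each with an estimated correlation). DFR fell in Col-0, WS and fus3-3, at −4.02 ± 0.36, −3.62 ± 0.26 and −2.23 ± 0.36. The storage list passed in lec2-1 (adjusted p = 0.037, and adjusted p = 0.38 with an estimated correlation), where AT1G03890 rose by 1.54 ± 0.10, and that call ended without lec2-1 replicate 1 of 12 DAF (0.054) or with the replicate number as a block. The seed coat gene BAN, which encodes anthocyanidin reductase, fell in all 5 genotypes, from −3.62 ± 0.29 in lec1-1 to −6.81 ± 0.35 in fus3-3. The genes past the threshold numbered 2421 in Col-0 (1125 higher, 1296 lower), 1209 in fus3-3 (567 and 642), 2041 in WS (861 and 1180), 1486 in lec1-1 (828 and 658) and 1733 in lec2-1 (887 and 846). Centring on reference genes moved the median change of all genes from 0.05 to −0.11 in Col-0, from 0.09 to −0.01 in WS and from 0.01 to −0.11 in lec2-1.

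The change from 8 to 12 DAF differed between mutant and wild type for photosynthesis genes in each of the 3 mutants, as the test of the difference showed. In fus3-3 the list's change exceeded that in Col-0 by a median of 3.19, with 10 of 11 members past the threshold. As a group, these genes had adjusted p = 5.1e-10, and adjusted p = 0.039 with an estimated correlation. The medians in lec1-1 and lec2-1 against WS were 6.06 (adjusted p = 6.5e-16, and adjusted p = 0.011 with an estimated correlation) and 4.98 (adjusted p = 8.9e-24, and adjusted p = 0.0037 with an estimated correlation), again with 10 members each. PSAN differed by 3.87 ± 0.41, 7.05 ± 0.24 and 5.37 ± 0.24 in fus3-3, lec1-1 and lec2-1. LEA genes differed the other way in 17 of 20 cases in fus3-3 (adjusted p = 9.4e-11, and adjusted p = 0.11 with an estimated correlation), with AT3G15670 at −7.40 ± 0.50, and in 12 cases, with 1 opposite, in lec1-1. The list test gave adjusted p = 0.00019, and adjusted p = 0.29 with an estimated correlation. In lec2-1, 4 LEA genes differed downwards and 1 upwards (adjusted p = 0.39). ER body genes differed upwards in 6 of 7 cases in fus3-3, 2 in lec1-1 and 4 in lec2-1, with JAL22 at 4.59 ± 0.38, 2.96 ± 0.36 and 3.75 ± 0.36 (adjusted p = 9.3e-07, 0.0059 and 3.3e-06, and adjusted p = 0.030, 0.14 and 0.030 with an estimated correlation). Flavonoid genes did so in 3, 5 and 4 of 5 cases, with DFR at 1.79 ± 0.51, 5.01 ± 0.36 and 4.86 ± 0.36 (adjusted p = 0.00017, 7.9e-05 and 9.3e-07, and adjusted p = 0.045, 0.059 and 0.030 with an estimated correlation).

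Among single genes, such differences upwards in fus3-3 included those of AT1G09750 at 8.30 ± 0.40, AT3G28220 at 8.09 ± 0.41, AT5G48490 at 7.46 ± 0.66 and AT1G32470 at 7.24 ± 0.19, and downwards those of AT2G38900 at −7.97 ± 0.36, AT1G54870 at −7.70 ± 0.90 and AT3G05260 at −7.13 ± 0.77 beside AT3G15670. In lec1-1 they included AT1G09750 at 8.59 ± 0.27, PORB at 8.27 ± 0.48, THI2.1 at 7.84 ± 0.27 and LHCB4.2 at 7.36 ± 0.32, against AT1G54870 at −6.52 ± 0.65, AT1G16850 at −5.96 ± 0.22, AT4G27530 at −5.59 ± 0.24 and AT3G53040 at −5.50 ± 0.43. In lec2-1 THI2.1, AT1G09750, PORB and AT5G48490 stood at 8.50 ± 0.27, 7.59 ± 0.27, 7.51 ± 0.48 and 5.77 ± 0.49, against AT4G29640 at −5.24 ± 0.18, AT1G49310 at −4.17 ± 0.30, M10 at −4.17 ± 0.70 and AT4G29570 at −3.66 ± 0.35. The storage list had a median of 0.26 in lec2-1 with no member past the threshold (adjusted p = 0.040, and adjusted p = 0.29 with an estimated correlation), a call that ended without lec2-1 replicate 1 (0.057) or 2 (0.060) of 12 DAF, lec2-1 replicate 2 of 8 DAF (0.073), WS replicate 2 of 12 DAF (0.094) or WS replicate 3 of 8 DAF (0.060), and with centring on reference genes (0.066). It also ended with the replicate number as a block. In fus3-3 that list had a median of −0.73 and a mean of −0.14 (adjusted p = 0.71). The genes past the threshold numbered 2111 in fus3-3 (1102 upwards, 1009 downwards; 1448 and 791 after centring on reference genes), 2140 in lec1-1 (1248 and 892) and 955 in lec2-1 (686 and 269). That centring moved the median difference of all genes from −0.04 to 0.16 in fus3-3 and from −0.12 to 0.00 in lec1-1.

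Set against lec2-1 at 8 DAF, lec1-1 had higher transcripts of 5 of 7 ER body and 10 of 20 LEA genes and lower transcripts of 2 of 5 storage genes. AT3G17520 stood at 10.94 ± 0.24 (SD, n = 3) in lec1-1 and near the floor of the array in lec2-1. AT2G47780, AT4G36600 and AT1G33790 were higher in lec1-1 by 5.20 ± 0.21, 5.09 ± 0.31 and 5.02 ± 0.27, and AT5G22810, AT1G71691, AT3G25160 and AT3G24250 were lower, at −7.02 ± 0.14, −5.99 ± 0.27, −5.84 ± 0.18 and −4.96 ± 0.27. ER body genes were higher in 5 of 7 cases, PYK10 by 3.92 ± 0.16 and JAL34 by 3.69 ± 0.20 (adjusted p = 1.3e-07, and adjusted p = 0.021 with an estimated correlation), and LEA genes in 10 of 20, LEA18 by 4.78 ± 0.17. Over all its members, AT3G17520 included, the LEA list had adjusted p = 3.9e-11, and adjusted p = 0.073 with an estimated correlation. It was not tested without AT3G17520. Storage genes were lower in 2 of 5 cases, AT1G03890 at −3.22 ± 0.10 and AT2G28490 at −1.54 ± 0.11 (adjusted p = 1.9e-08, and adjusted p = 0.021 with an estimated correlation), and photosynthesis genes in 3 of 11, PRK at −1.56 ± 0.17, LHCB4.3 at −1.44 ± 0.13 and PSAN at −1.11 ± 0.17. Camera put the list at adjusted p = 1.3e-07, and adjusted p = 0.054 with an estimated correlation. OLEO3 was lower in lec1-1, at −1.25 ± 0.09, as were AGL67 at −1.98 ± 0.30 and BBM at −1.15 ± 0.30. In all, 677 genes passed the threshold, 302 higher and 375 lower, or 411 and 284 after centring on reference genes, which moved the median of all genes from −0.00 to 0.14.

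At 12 DAF, AT3G17520 stood at 12.35 ± 0.20 (SD, n = 3) in lec1-1 against 2.33 ± 0.06 in lec2-1, and AT5G38020, AT3G28310 and the xyloglucan enzyme gene XTH19 (AT4G30290) were higher in lec1-1 by 5.48 ± 0.34, 5.12 ± 0.24 and 4.61 ± 0.26. AT5G22810, AT1G71691, AT3G25160 and AT4G19380 were lower, at −6.48 ± 0.14, −5.45 ± 0.27, −4.99 ± 0.18 and −4.60 ± 0.18. Storage genes were lower in lec1-1 in 4 of 5 cases, with AT4G36700 at −2.78 ± 0.09 and AT2G28490 at −1.28 ± 0.11 (adjusted p = 1.1e-05, and adjusted p = 0.054 with an estimated correlation), and oil body genes in 4 of 4, with OLEO3 at −2.41 ± 0.09. AGL67 and EEL were lower, at −3.05 ± 0.30 and −1.77 ± 0.13, and FaTA was lower, at −3.15 ± 0.16. ER body genes were higher in lec1-1 in 5 of 7 cases, PYK10 by 3.31 ± 0.16, and JAL23 was lower, at −2.13 ± 0.14. This shift had adjusted p = 0.0014, adjusted p = 0.084 with an estimated correlation and 0.17 with centring on reference genes. Of the photosynthesis genes, LHCB4.2 was higher by 1.13 ± 0.23 and LHCB4.3 was lower, at −2.39 ± 0.13, and the list's shift had adjusted p = 0.025, adjusted p = 0.37 with an estimated correlation, 0.58 with centring and 0.069 without lec2-1 replicate 2. LEA genes were higher in 6 cases and lower in 4, with a median of −0.08 and a mean of 0.80 (adjusted p = 0.38). In all, 1469 genes passed the threshold, 736 higher and 733 lower, or 1267 and 466 after centring on reference genes, which moved the median of all genes from −0.03 to 0.24.

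The calls of the 3 mutants overlapped at both ages. At 12 DAF fus3-3 and lec1-1, which have no array in common, shared 1055 higher genes, where independent lists of these sizes would share 165, and 974 lower genes against 152. At 8 DAF they shared 307 against 25.6 and 337 against 32.7. For fus3-3 and lec2-1 the shared calls at 8 DAF were 94 higher against 8.62 and 68 lower against 6.11, and at 12 DAF 544 against 81.0 and 102 against 20.2. For lec1-1 and lec2-1, both set against the same WS arrays, the shared calls were 166 higher against 10.2 and 110 lower against 8.31 at 8 DAF, and 633 against 70.2 and 146 against 17.5 at 12 DAF. In 100 simulations of unchanged groups set against the WS arrays, which hold hardly any calls and so say nothing of shared real calls, the shared calls were 0. The covariance of the simulated log2 changes was 0.012 at both ages, against 0.201 at 8 DAF and 0.620 at 12 DAF in the data. With 3 WS arrays per age the controls were not split, and part of the excess of lec1-1 and lec2-1 may come from the shared arrays. PYK10, NAI2 and JAL34 were among 88 genes called higher in all 3 mutants at 8 DAF, where independent lists would give 0.410, and at 12 DAF 535 genes were called higher in all of them against 8.39. The genes called lower in all 3 numbered 60 at 8 DAF against 0.353 and 91 at 12 DAF against 2.01.

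Within a mutant, 352 genes were called higher and 354 lower at both ages in fus3-3, 387 and 439 in lec1-1, and 102 and 18 in lec2-1. Calls in opposite directions at the 2 ages numbered 46 higher at 8 DAF and lower at 12 DAF in fus3-3, among them the LEA genes AT3G53040 and AT1G72100, and 39 the other way, among them LHCB4.2 and PSAN, where independent lists would give 61.8 and 67.7. In lec1-1 these numbered 22 and 71 against 63.0 and 79.8, and in lec2-1 1 and 17 against 2.82 and 7.31.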

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

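The tests of seeds further along in development, of silique tissue, of RNA quality in lec2-1 at 12 DAF as a part of its own, and of the neighbours of AT3G17520 and AT3G27420 address results that had been seen first. The others below were set before the data were examined.

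The change from 8 to 12 DAF differed between mutant and wild type for 2111 genes in fus3-3, 2140 in lec1-1 and 955 in lec2-1, a difference between groups by its own test. By the same test, list medians differed by 3.19, 2.56 and 1.79 for photosynthesis, ER body and flavonoid genes in fus3-3, by 6.06 for photosynthesis genes in lec1-1, and by 4.98, 1.34 and 2.55 for photosynthesis, ER body and flavonoid genes in lec2-1. The single genes flagged by it in fus3-3 were AT1G09750 (8.30), AT3G28220 (8.09), AT5G48490 (7.46), AT1G32470 (7.24), AT2G38900 (−7.97), AT1G54870 (−7.70), AT3G15670 (−7.40) and AT3G05260 (−7.13). In lec1-1 they were AT1G09750 (8.59), PORB (8.27), THI2.1 (7.84), LHCB4.2 (7.36), AT1G54870 (−6.52), AT1G16850 (−5.96), AT4G27530 (−5.59) and AT3G53040 (−5.50), and in lec2-1 THI2.1 (8.50), AT1G09750 (7.59), PORB (7.51), AT5G48490 (5.77), AT4G29640 (−5.24), AT1G49310 (−4.17), M10 (−4.17) and AT4G29570 (−3.66). Each group had 3 arrays, so the rule for an array far from the others was not applied.

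Of 9233 probe sets paired with several genes or none, which the comparisons did not use, 1016 and 2928 passed the threshold in fus3-3 at 8 and 12 DAF, 1335 and 2623 in lec1-1, and 401 and 937 in lec2-1.

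Other splits of the same arrays were counted for every comparison. In the 6 mutant comparisons, the 5 age comparisons and the 2 of lec1-1 against lec2-1, 1 of 10 splits, the real one, gave as many genes, and the splits are too few for a share under 0.05. The real counts and the highest among the other splits were 1105 and 1, and 3130 and 1, for fus3-3 at 8 and 12 DAF, 1406 and 1, and 2709 and 1, for lec1-1, and 358 and 0, and 854 and 3, for lec2-1. With age they were 2421 and 0 in Col-0, 1209 and 2 in fus3-3, 2041 and 1 in WS, 1486 and 1 in lec1-1 and 1733 and 0 in lec2-1, and for lec1-1 against lec2-1 677 and 3, and 1469 and 1. For the difference of age changes, 11 of 100 splits gave as many as the 2111 genes of fus3-3 (highest other 3929), 8 of 100 as many as the 2140 of lec1-1 (3875) and 1 of 100, the real one, as many as the 955 of lec2-1 (797). The shares in fus3-3 and lec1-1 were over the 0.05 set beforehand for chance. The splits that called many genes kept the arrays of 1 age whole, 10 of 21 such splits reaching the real count in fus3-3, 7 of 17 in lec1-1 and 0 of 19 in lec2-1, while splits mixing both ages called at most 1 gene. A split that keeps 1 age whole holds the real difference between mutant and wild type at that age, so its count is not one that chance alone would give. Mixed splits put any difference between the groups into the spread within them, so their low counts do not tell its source. The splits therefore do not decide whether chance gave the counts for the differences of age changes in any mutant.

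Photosynthesis genes were higher at 12 DAF, 8 of 11 in fus3-3 (adjusted p = 0.00023, and adjusted p = 0.15 with an estimated correlation) and 10 in lec1-1 and in lec2-1, while LHCB4.3 fell in fus3-3 and lec1-1. A chromosome segment from another parent around the mutated gene is argued against as the source of the calls by ratios of called shares, neighbours to other genes, of 1.01 for FUS3, 1.36 for LEC1 and 1.36 for LEC2, and degraded RNA is argued against in lec2-1 at 12 DAF, where GAPDH and actin 3' minus 5' signals differed by −0.061 and −0.012, both under 1 SD. It stays open in the 5 other mutant comparisons, 0 of them with both controls higher by over 1 SD, since over all 6 GAPDH was lower by over 1 SD in 4 and actin higher by over 1 SD in 5. A delay of seed development along the normal course could give 32.9% of the genes called in fus3-3, 45.8% in lec1-1 and 59.0% in lec2-1, which changed with age in the other wild type in that direction (4.89%, 4.28% and 4.45% in the opposite one); the share in lec2-1 met what a delay needed, but 425 of its 504 genes were higher calls, and of the genes rising with age only 76 of 1125 were lower there, against 485 of 861 in fus3-3 and 562 of 1125 in lec1-1. Green silique tissue among the seeds stays open with 1 measured marker, ALC, which rose by 1.67, 2.06 and 1.57 in fus3-3, lec1-1 and lec2-1, against mean changes of the photosynthesis list of 1.46, 3.90 and 3.61, so that it reached the list's mean in fus3-3, though not its median of 2.26, and stayed below the mean in lec1-1 and lec2-1.

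The actin 3' minus 5' signal was higher than in Col-0 by 1.04 in fus3-3 at 12 DAF (pooled SD 0.54), with 6.78 on replicate 2 against 5.55 and 5.40 on the other arrays, and higher than in WS by 0.34 in lec1-1 at 8 DAF (pooled SD 0.07); without that replicate 2, 3194 genes passed the threshold, against 3130.

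At 8 DAF, 12 of 20 LEA genes rose in fus3-3, and 9 rose and 2 fell in lec1-1 (adjusted p = 1.5e-10 and 0.00013, and adjusted p = 0.13 and 0.27 with an estimated correlation). Seeds further along the normal course than wild-type seeds of the same age would raise the genes that rise with age in the other wild type. These had a median change at 8 DAF of −0.21 in lec1-1 (quartiles −0.74 and 0.14), which met what was set against it there, and of 0.0085 in fus3-3 (quartiles −0.36 and 0.52). At 12 DAF, however, 562 of 1125 such genes were lower in lec1-1 and 485 of 861 in fus3-3. A lowering of these genes by the mutations could hide a later stage, so the medians leave it open in both mutants. A direct effect of the mutations on LEA genes was not tested.

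AT3G17520 and AT3G27420 lay near the floor of the array in lec2-1 at both ages. Neighbours with enough signal to show a loss lay at least 8 genes from AT3G17520 and at least 6 from AT3G27420, and 0 and 0 of them fell past the threshold at both ages. This argues against the loss of a chromosome stretch that reaches them. The loss of a shorter stretch or of the single gene stays open, since the closer tested genes had a log2 signal under 3 in WS too, as does an effect of the lec2-1 mutation, which was not tested.

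The arrays of Col-0 at 12 DAF, with replicate numbers in 2 parts, had a median SD over genes 1.34 times the median of the other 9 groups. This met what was set against arrays of 1 RNA sample deposited as 3. Within the Col-0 set the value was 0.128, against 0.095 in Col-0 at 8 DAF and 0.129 and 0.143 in fus3-3 at 8 and 12 DAF. No arrays known to share 1 RNA sample were at hand, so the spread does not settle the question.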

How the results depend on the processing

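All alternatives here were written down before the data were examined. The counts stayed within 1.5 times the main count in all 16 comparisons with quantile normalization again, centring, dim genes left out, only the groups compared, all 30 arrays in 1 fit, trended and robust variances, and an adjusted p under 0.01. The 152 results for genes named by the size of their change, counted per comparison, kept their calls in the 5 settings tried for them. These were the largest rises and falls, so that a kept call says little. The other list members named above, some close to the threshold, were not among them. Leaving out each array gave 910 to 1129 and 2989 to 3208 genes for fus3-3 at 8 and 12 DAF, 1362 to 1436 and 2687 to 2768 for lec1-1, and 315 to 379 and 797 to 927 for lec2-1. With all probe sets except controls, which tests more probe sets, the counts were 2144 and 6078 for fus3-3, 2751 and 5347 for lec1-1, and 764 and 1795 for lec2-1; 4661, 2461, 3950, 2945 and 3395 with age in Col-0, fus3-3, WS, lec1-1 and lec2-1, 4168, 4174 and 1967 for the differences of age changes, and 1356 and 2994 for lec1-1 against lec2-1. With no fold minimum, which only adds genes, they were 2224 and 5615, 3931 and 9069, and 1532 and 4934 for the mutants, 4364, 2125, 8025, 3937 and 4276 with age, 6490 and 2638 for the differences in lec1-1 and lec2-1, and 2430 and 4202 for lec1-1 against lec2-1.

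Of 128 list shifts, 41 lost their call with an estimated correlation, 5 with centring and 1 with fry, while fry added 38 calls and centring 6. Fry asks whether a list's genes move one way at all, and camera whether they move more than other genes, so these calls answer another question. Leaving out each array in turn kept 887 list results, ended 15 calls and added 10. The reference genes reversed in WS at 12 against 8 DAF, up with fry at an adjusted p of 0.0396 and down with camera at 0.94; the cause was not tested. The shared counts of the overlaps moved in 12 of 12 cases with no fold minimum and in 0 of 12 with dim genes left out. Their ratio to independent lists was smaller in each case with dim genes left out. For the higher genes of fus3-3 and lec1-1 it went from 12.0 to 7.66 at 8 DAF and from 6.39 to 4.19 at 12 DAF. The signal of the arrays limits what can be read from genes near the floor.

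With the replicate number as a block, the counts were 1090 and 3122 for fus3-3, 1405 and 2708 for lec1-1, 357 and 852 for lec2-1, and 2426, 1193, 2041, 1483 and 1736 with age. They were 2095, 2127 and 922 for the differences of age changes, and 675 and 1466 for lec1-1 against lec2-1. In fus3-3 at 12 against 8 DAF, where deviations correlated by number, the block changed no list call. It was fitted over the whole Col-0 set, and in Col-0 these correlations with age were only 0.017 to 0.062. A pairing of the fus3-3 arrays alone was therefore not tested. Elsewhere the arrays share only a number, with correlations of −0.17 to 0.23, and the block took 3 list calls past 0.05, auxin in fus3-3 at 8 DAF (0.054) and seed storage in lec2-1 with age (0.050) and in its difference from WS (0.053).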

Other observations

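The tests of gene families, of adjacent genes, of the chromosome 4 genes and of JAL33 below were all chosen after the data were seen.

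At 8 DAF, 3 of the 9 annotated genes from AT4G29570 to AT4G29650 on chromosome 4 were higher in both lec mutants, and none of the 9, all of them tested, passed the threshold in fus3-3. AT4G29570, AT4G29640 and AT4G29650 rose by 5.16 ± 0.25, 4.89 ± 0.13 and 2.73 ± 0.27 log2 units in lec1-1 and by 5.34 ± 0.25, 5.07 ± 0.13 and 3.52 ± 0.27 in lec2-1, against −0.35 ± 0.33, 0.59 ± 0.42 and −0.26 ± 0.16 in fus3-3, which was not tested against them. At 12 DAF, AT4G29570 rose in lec2-1 by 1.68 ± 0.25. Of the other 6, AT4G29620 rose in lec2-1 by 1.14 ± 0.17 and AT4G29590 fell in lec1-1, at −1.24 ± 0.10, both at 8 DAF, and 4 were not called in either lec mutant. AT4G29590 also fell at 12 DAF, at −1.17 ± 0.10 in lec1-1 and −1.68 ± 0.17 in fus3-3. In fus3-3 at 8 DAF it stood at −0.99 ± 0.17 (adjusted p = 0.0040), short of 2-fold.

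JAL33 ran from 2.60 to 3.49 on the 18 arrays of the WS set and from 2.58 to 11.24 on the 12 arrays of the Col-0 set. It was kept in the ER body list in both sets. Whether its probe set can show a rise in the WS background was not tested.

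In the order of the 13333 tested genes along the chromosomes, pairs of neighbours called in the same direction were counted. They were more numerous than under 10000 permutations in 7 of 12 cases at adjusted p under 0.05. Genes not tested may lie between such neighbours, and the permutations treat all tested genes as equally likely to be called. Pairs of higher genes numbered 58 against 34.4 in lec2-1 at 12 DAF and 209 against 143 in lec1-1 at 12 DAF, and pairs of lower genes 224 against 175 in fus3-3 at 12 DAF, each at p = 1e-04, the smallest that these permutations can give (adjusted p = 4e-04). In fus3-3 higher genes gave 32 pairs against 21.7 at 8 DAF (adjusted p = 0.033) and 231 against 190 at 12 DAF (adjusted p = 0.0021), and in lec1-1 46 against 30.1 at 8 DAF (adjusted p = 0.0064), with pairs of lower genes at 162 against 131 at 12 DAF (adjusted p = 0.0064).

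Among 24 families of genes sharing a symbol, each with at least 8 members, none passed in 144 camera tests, the lowest adjusted p being 0.061.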
